A study of Mus musculus with 6 samples.

How the data were processed

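RNA was sequenced from myotubes of C2C12, an immortalised mouse myoblast line whose cells fuse into multinucleated muscle fibres when serum is lowered. Fully differentiated cultures received 10 µM Sardomozide, an inhibitor of S-adenosylmethionine decarboxylase (the enzyme encoded by Amd1), or the solvent DMSO for 72 h, and 3 libraries of each kind were analysed. Per the labels' protocols, total RNA was extracted on columns and sequenced on an Illumina NovaSeq with paired reads of 150 bases. The labels do not say whether the 3 libraries of a group came from separate cultures, so all p-values measure only the spread between these libraries, which may be technical.

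The authors deposited one table of raw read counts per gene symbol for each library, with 24411 symbols and no summary lines. The submitters' processing notes name STAR, StringTie, DESeq2 and the builds GRCm38 and mm10. Their versions, the role of each tool, the gene annotation, the treatment of reads that match several places and the use of strand are not given in the sources used here. A gene that shares sequence with a near-identical copy, or that overlaps another gene, can therefore have lost or gained reads in the deposited counts. Coordinates were taken from the GENCODE M21 annotation of GRCm38, which has the same symbol for 12597 of the 13076 genes tested.

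Groups were taken from the labels. Library totals ran from 25496323 to 36709804 counts, and 7344 symbols had no count in any library. A count of 0 allows up to 3 counts, or 0.0817 to 0.118 CPM (counts scaled by library size) depending on the library, and this limit covers counting error only. Replicates of a group were compared by a chi-square test of their counts over genes with at least 10 counts in a pair. The statistic per degree of freedom lay between 5.45 and 16.1, so no pair agreed within sampling noise and all 6 libraries were kept. It was 5.45 to 6.88 for pairs of DMSO libraries and 9.06 to 16.1 for pairs of Sardomozide libraries. The statistic also grows with library totals. The main test fitted the same dispersion to both groups.

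Genes were filtered with filterByExpr (at least 10 counts scaled to library size in enough libraries, and 15 in total), library sizes were scaled by TMM, and the groups were compared with the two-sided quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, treatment as the single term). P-values were adjusted by Benjamini-Hochberg over the 13076 genes tested, and genes with an adjusted p under 0.05 were called. A fold of 1.5 was used to describe the size of changes, as a filter on the estimate. CPM values use TMM-scaled library sizes. Errors after log2 fold changes are standard errors derived from the fold change and the F statistic of edgeR's test. Errors after CPM values are standard deviations over 3 libraries. Single values per library were compared with a two-sided exact permutation test, which cannot give a p below 0.1 for 3 against 3.

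Lists of 47 gene groups were fixed, covering polyamine and methionine metabolism, muscle structure and differentiation, protein synthesis and breakdown, stress responses, proliferation, energy and lipid metabolism, signalling, and markers of other cell types. The 41 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 41 lists. Camera was repeated with a correlation estimated from the libraries, and fry was run beside it. For each list, genes were also counted after adjustment over the list alone.

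The genes named in the text followed a rule. It took every tested polyamine gene with Amd1, and the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 2 and no overlap between the groups, without predicted genes, clone names and pseudogenes. It added up to 4 called members of each list with the smallest adjusted p (2 members where none was called) and the 5 genes with the smallest adjusted p. Some genes that the rule takes are not reported here. Myog, Chrng, Musk, Pax7, Myf5 and Rn45s, the counts of Oaz1 and Hnrnpa1, and the individual members of the ERK, YAP and CREB target lists fall outside this rule and were chosen after their values were seen. The groups, the main test, the lists, the rule and most alternatives were fixed before the data were examined.

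Other settings chosen in advance were RLE, upper-quartile and no scaling factors, DESeq2 1.42.0, limma-voom, no filter and a stricter filter, the replicate number as a block, estimation without robustness, a test against a 1.2-fold change, a threshold of 0.01, and leaving out each library in turn. Thinning all libraries to the smallest total, removing each library's trend on GC content and transcript length, and leaving out the ribosomal precursor Rn45s were added after seeing the data. The steps were tested on simulated counts with the means and library sizes of this comparison. Of the planted changes among 12980 genes tested, 44.6% were recovered at 1.2-fold, 74.2% at 1.5-fold and 93.8% at 2-fold, and 5 of the 144 calls were false. Of 200 random lists, 5 had an unadjusted camera p under 0.05. Each simulated gene had the dispersion of the fitted trend, not its own, and 200 changes were planted. In the real libraries 16.3% of genes were called. The rates of recovery and of false calls therefore need not hold for the real comparison. The simulated genes varied independently of each other. The random lists therefore cannot show how the preset correlation performs for real lists, whose genes can move together.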

Results

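The data are read counts per gene from 6 libraries of C2C12 myotubes, 3 from cultures given DMSO and 3 from cultures given 10 µM Sardomozide for 72 h. The comparison asks how the transcripts of differentiated muscle cells differ when Amd1 is inhibited. Totals were 25496323, 32108033 and 29792122 counts in the DMSO libraries and 36709804, 34456270 and 30820423 in the Sardomozide libraries. The totals of the groups gave p = 0.2 in a two-sided exact permutation test, where 0.1 is the smallest p possible. Between 15000 and 15332 genes had at least 1 count in a library.

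Myotubes given Sardomozide had lower levels of Smox and 4 other polyamine genes, of which Slc18b1 lost its call in several fits without a library. Lower too were Chrne, Colq and Ache, which act at the neuromuscular junction, and Mybpc1, Csrp3 and Tcap, which act in or at the sarcomere. Of 25 junction and denervation genes 6 rose and 10 fell, and of 46 sarcomere genes 3 rose and 12 fell. Camera called neither list (adjusted p = 0.187 and 0.184). Of 41 ribosome assembly genes 16 rose and 0 fell, and of 20 aminoacyl-tRNA synthetase genes 11 rose (7 without DMSO replicate 3) and 0 fell. Camera called both lists (adjusted p = 2.28e-06 and 0.000145), with adjusted p = 0.416 with an estimated correlation for each. Of 13076 genes tested, 2135 (16.3%) passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1030 higher and 1105 lower. Most of these changes were small, with a median fold of 1.2 among genes that passed. A change of at least 1.5-fold was seen for 121 genes that rose and 174 that fell, and one of at least 2-fold for 48 and 76. With the stricter filter on low counts, 139 genes instead of 295 changed by at least 1.5-fold. The groups separated on the first principal component, which held 39.8% of the variance, and did not overlap for 2093 of the 2135 genes. Over all genes tested, 33.5% did not overlap, against 10% by chance. The number of genes called was lower whichever library was left out (1326 to 1952), and lowest without DMSO replicate 1. Such fits have fewer samples, so a lower count or a lost call does not by itself show dependence on that library. All of them had the same number of libraries, however. Without DMSO replicate 1, 2 or 3 the count was 1326, 1603 and 1443. Without Sardomozide replicate 1, 2 or 3 it was 1952, 1867 and 1660. Sample number therefore does not account for the lower counts without a DMSO library, and the cause was not tested. On the second principal component (16.5% of the variance), DMSO replicate 1 lay at 19.2 and DMSO replicates 2 and 3 at −8.72 and −12.5. Without DMSO replicate 3, 672 genes rose.

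**Figure D1:**
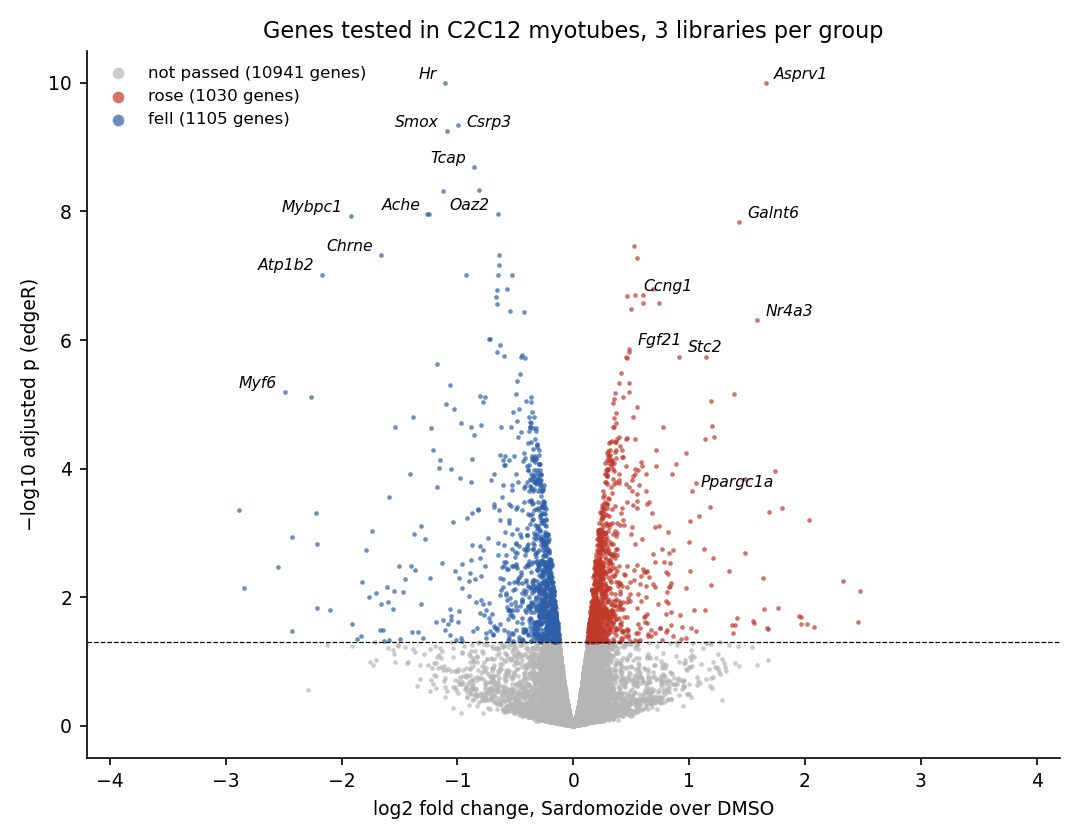
Each point is 1 of 13076 genes, with the log2 fold change of Sardomozide over DMSO on the horizontal axis and the negative log10 of edgeR's adjusted p on the vertical axis, and the dashed line at an adjusted p of 0.05. Red points are the 1030 genes that rose and blue points the 1105 that fell, and most lie near 0 on the horizontal axis.

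The target gene, Amd1 (chromosome 10, 40287458 to 40302186, GRCm38), had 0, 3 and 0 counts in the DMSO libraries and 0, 0 and 0 in the Sardomozide libraries. Its near-identical copy Amd2 (chromosome 10, 35708675 to 35711892) had 0 counts in all 6. These values lie at or under the limit of 3 counts that a count of 0 allows, so a difference in Amd1 was not detectable and the counts give no check of the labels. Oaz1, which encodes an antizyme that lowers ornithine decarboxylase, had 0, 0 and 0 counts with DMSO and 0, 0 and 1 with Sardomozide. The drug acts on the enzyme, and the counts do not measure enzyme activity.

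Among polyamine genes, Smox, which encodes spermine oxidase, fell by 52.9%, from 50.4 ± 1.32 to 23.8 ± 1.22 CPM (SD, n = 3; log2 fold change −1.09 ± 0.064, edgeR adjusted p = 5.7e-10). The gene lies on chromosome 2 from 131491496 to 131525922. Oaz2, another antizyme gene, fell from 111 ± 3.3 to 70.7 ± 1.96 CPM (log2 fold change −0.65 ± 0.047, edgeR adjusted p = 1.1e-08). Sat1, whose product acetylates spermidine and spermine for export and breakdown, fell by 25.4%, and Sms, the spermine synthase gene, fell by 19.3% (edgeR adjusted p = 0.000202 and 0.000796). Slc18b1, a vesicular polyamine transporter gene, fell by 22.4% (edgeR adjusted p = 0.0169). That call was lost without DMSO replicate 1 or 3 or Sardomozide replicate 1 or 2 (adjusted p = 0.0875, 0.05, 0.072 and 0.0525). Of 17 tested polyamine genes, 0 rose, 5 fell and 12 did not pass, and adjusted over the list alone 1 rose and 8 fell. The genes that did not pass included Odc1, the ornithine decarboxylase gene (log2 fold change −0.11 ± 0.042, edgeR adjusted p = 0.0947), Azin1 (0.12 ± 0.042, 0.0542) and Azin2 (−0.29 ± 0.099, 0.0505). Azin1 passed without DMSO replicate 2 or Sardomozide replicate 1 (adjusted p = 0.046 and 0.0488), and Azin2 passed with RLE scaling factors, no filter and the stricter filter (0.0495, 0.0441 and 0.0458). Srm and Paox had log2 fold changes of −0.04 ± 0.077 and −0.08 ± 0.14. Camera placed the list below other genes (adjusted p = 0.0242), with adjusted p = 0.416 with an estimated correlation. Fry gave the list an adjusted p of 0.00675. Without DMSO replicate 3 the list had a camera adjusted p of 0.0582, and over the libraries left out in turn the value ran from 0.017 to 0.0582. In the methionine cycle and salvage list, Mtrr rose, Gamt fell and 19 of 21 members did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.774). None of the 4 tested hypusine and eIF5A genes passed, nor when adjusted over the list alone; 4 tested members are too few for the list test, and their median lay above 0 and their mean below.

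**Figure D2:**
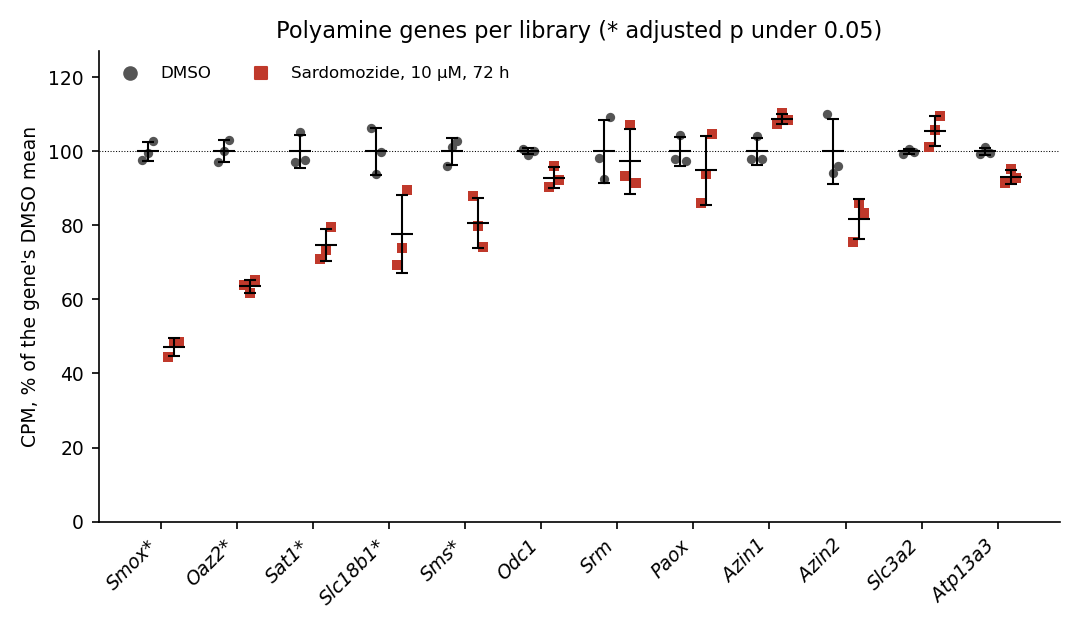
CPM of 12 polyamine genes in each library, as a percent of the gene's DMSO mean, with circles for DMSO, squares for 10 µM Sardomozide at 72 h, and bars for the mean ± SD of 3 libraries. Starred genes passed edgeR's test at an adjusted p under 0.05, and Smox, at 50.4 CPM with DMSO and 23.8 CPM with Sardomozide, shows the lowest treated values.

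Among called genes with a mean log2 CPM of at least 2 and no overlap between the groups, the largest rises were those of Asprv1, an aspartic protease gene, from 10.3 ± 0.398 to 32.7 ± 1.9 CPM (log2 fold change 1.66 ± 0.083), and Nr4a3, an orphan nuclear receptor gene, from 3.94 ± 0.906 to 11.9 ± 1.27 CPM (1.58 ± 0.15). Galnt6, a gene of O-linked glycosylation, rose from 51.8 ± 1.84 to 140 ± 15.8 CPM (log2 fold change 1.43 ± 0.07), and Nptx1 from 54.1 ± 3.47 to 126 ± 16.2 CPM. Nmrk2, a nicotinamide riboside kinase gene of muscle, rose from 13.1 ± 2.58 to 30 ± 2.41 CPM. Bglap2, Mreg, Slc5a5, Fam65b and Adm rose with log2 fold changes between 1.06 for Adm and 1.39 for Bglap2. Bglap2 shares sequence with other osteocalcin genes, so its counts are uncertain. The largest falls above the same level were those of Atp1b2, a sodium pump subunit gene, from 23.6 ± 1.69 to 5.24 ± 1.43 CPM (log2 fold change −2.17 ± 0.14), and Mybpc1, which encodes slow myosin-binding protein C, from 157 ± 17.7 to 41.4 ± 2.13 CPM (−1.92 ± 0.076). Nfatc2, Mylk3, Myoz1, Best3 and the fatty acid transporter gene Cd36 fell with log2 fold changes of −1.38, −1.23, −1.21, −1.18 and −1.18. Among the genes with the smallest adjusted p were Hr, a corepressor gene (84.1 ± 0.568 to 38.9 ± 2.92 CPM), and Csrp3, which encodes muscle LIM protein (64.7 ± 2.02 to 32.4 ± 1.13 CPM). EdgeR's adjusted p for the genes of this paragraph ran from 1e-10 for Asprv1 and Hr to 0.000194 for Cd36.

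Genes of the neuromuscular junction moved in both directions. Chrne, the acetylcholine receptor subunit of adult junctions, fell from 12.6 ± 1.35 to 3.99 ± 0.445 CPM (log2 fold change −1.66 ± 0.13, edgeR adjusted p = 4.75e-08). Ache, the acetylcholinesterase gene, and Colq, whose product anchors that enzyme, fell with log2 fold changes of −1.25 ± 0.09 and −1.26 ± 0.091 (edgeR adjusted p = 1.1e-08 for both), and Etv5 fell by 0.66 on the log2 scale. Of 25 tested members of the junction and denervation list, 6 rose, 10 fell and 9 did not pass, and adjusted over the list alone 7 rose and 11 fell. Musk, the receptor kinase that organises the junction, fell (−0.24 ± 0.045), whereas Chrng, the receptor subunit of embryonic muscle, and Myog, the gene of the differentiation factor myogenin, rose (0.22 ± 0.046 and 0.24 ± 0.043). These 3 genes were singled out after their values were seen. Camera did not call the list (adjusted p = 0.187), and fry, which asks whether its genes moved one way on balance, gave an adjusted p of 0.00733.

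Of 46 sarcomere genes tested, 3 rose, 12 fell and 31 did not pass, and adjusted over the list alone 5 rose and 14 fell. Tcap, which encodes the Z-disc protein telethonin, fell from 72.5 ± 2.8 to 40.1 ± 0.928 CPM (edgeR adjusted p = 2.04e-09). Perinatal myosin Myh8 and embryonic light chain Myl4 fell with log2 fold changes of −0.63 ± 0.056 and −0.49 ± 0.053. Among embryonic isoforms 0 of 7 rose and 2 fell, and among adult fast isoforms 0 of 12 rose and 2 fell, namely Myh2 (−0.59 ± 0.07) and Atp2a1 (−0.27 ± 0.046). Adjusted over the list alone, 1 embryonic isoform rose and 2 fell, and 0 fast isoforms rose and 2 fell. Camera called none of the 3 lists (adjusted p = 0.184, 0.436 and 0.464). The medians of all 3 were above 0 (0.009, 0.05 and 0.009 on the log2 scale) while the means (−0.13, −0.12 and −0.08) and the tests pointed down. Leaving out Sardomozide replicate 1 or DMSO replicate 1 brought the sarcomere list to adjusted p = 0.00704 and 0.049. Without DMSO replicate 2 or Sardomozide replicate 3, 5 sarcomere genes and 1 embryonic isoform rose, and without Sardomozide replicate 1, 4 fast isoforms fell.

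Among 21 myogenic and fusion genes, 7 rose, 4 fell and 10 did not pass, and adjusted over the list alone 9 rose and 7 fell. Myf6, a myogenic factor gene of mature fibres, fell from 3.91 ± 0.526 to 0.702 ± 0.312 CPM (log2 fold change −2.49 ± 0.29, edgeR adjusted p = 6.42e-06), and Itgb1bp2 fell by 0.53 on the log2 scale. Mef2a and the cell cycle inhibitor gene Cdkn1c rose (0.34 ± 0.041 and 0.78 ± 0.076). Camera did not call the list (adjusted p = 0.809), and its median and mean lay below 0 while the test pointed up. Of 29 calcium handling genes 5 rose and 7 fell, with Cacna1s, Stim1 and Atp2a1 lower and Casq2 higher (log2 fold changes −0.37, −0.37, −0.27 and 0.36; camera adjusted p = 0.774). Of 24 dystrophin complex and membrane genes 2 rose, Dysf and Dag1, and 4 fell, Cav3 and Sspn among them (camera adjusted p = 0.239). Adjusted over the list alone, 5 calcium handling genes rose and 8 fell, and 2 membrane genes rose and 4 fell. Of the calcium handling genes, 3, 2 and 3 rose without DMSO replicate 1, DMSO replicate 3 and Sardomozide replicate 2, and 4 fell without DMSO replicate 2.

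**Figure D3:**
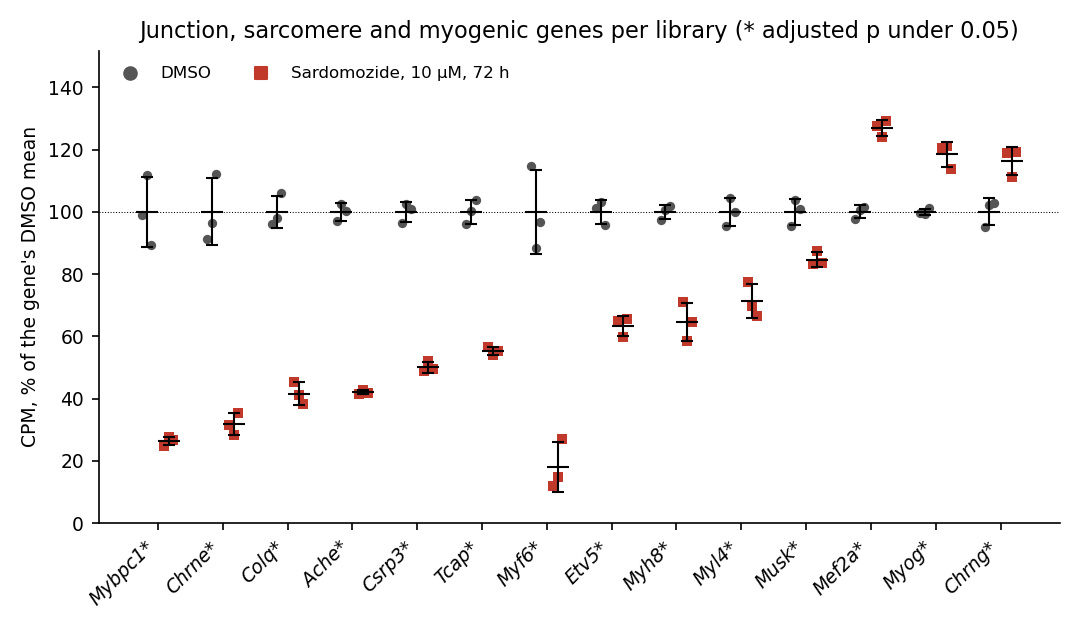
CPM of 14 junction, sarcomere and myogenic genes in each library, as a percent of the gene's DMSO mean, with circles for DMSO, squares for Sardomozide, and bars for the mean ± SD of 3 libraries. All 14 passed edgeR's test, and the treated values of Mybpc1 (157 to 41.4 CPM) and Chrne (12.6 to 3.99 CPM) lie far below those of DMSO, whereas Mef2a, Myog and Chrng lie above.

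Of 41 ribosome assembly genes, 16 rose, 0 fell and 25 did not pass, and adjusted over the list alone 21 rose and 0 fell. Nop2, Rrp12, Gnl3 and Polr1a, the gene of the largest RNA polymerase I subunit, rose with log2 fold changes of 0.33 ± 0.048, 0.33 ± 0.049, 0.32 ± 0.052 and 0.32 ± 0.044. Of 20 aminoacyl-tRNA synthetase genes, 11 rose, 0 fell and 9 did not pass, and adjusted over the list alone 12 rose. Without DMSO replicate 3, 7 rose. Farsa, Yars, Iars and Nars led with log2 fold changes of 0.31, 0.26, 0.23 and 0.19. Camera called both lists (adjusted p = 2.28e-06 and 0.000145), with adjusted p = 0.416 with an estimated correlation for each. Before adjustment, camera with the estimated correlation gave p = 0.0134 for ribosome assembly and 0.0703 for the synthetases. Fry gave adjusted p = 0.00675 and 0.0082. The ribosomal RNA precursor Rn45s took 1.01 ± 0.141% of the counts with DMSO and 1.32 ± 0.129% with Sardomozide, p = 0.1 in a two-sided exact permutation test, the smallest p possible, and its edgeR adjusted p was 0.107. The closest libraries were DMSO replicate 1 (1.168%) and Sardomozide replicate 3 (1.174%). Rn45s passed as a rise with limma-voom (adjusted p = 0.00457) and with estimation without robustness (0.00542). It also passed without DMSO replicate 1 (0.000805) and without Sardomozide replicate 3 (0.0134). Whether its share of the counts reflects its transcription was not tested. Of 45 ribosomal protein genes, 4 rose, Rpl13 and Rps7 among them, and 1 fell, Rpl10a, with the same counts adjusted over the list alone (camera adjusted p = 0.239). Its camera adjusted p was 0.0304 without Sardomozide replicate 1 and 0.0326 after GC and length correction. Rpl10a had an edgeR adjusted p of 0.0519 without DMSO replicate 1. Of 34 translation factor genes 5 rose and 3 fell (6 and 3 adjusted over the list alone), with Eif2s2 higher (0.29 ± 0.041) and Eif4g2 lower (−0.20 ± 0.043), and Eef1a2, the elongation factor gene of mature muscle, falling from 2.09 ± 0.637 to 0.625 ± 0.0555 CPM. Camera did not call it (adjusted p = 0.163), and its mean lay below 0 while the median and the test pointed up. Of the translation factor genes 2 or 3 rose whichever library was left out. Of the ribosomal protein genes 2 rose without DMSO replicate 2 or 3 or Sardomozide replicate 2, and 2 and 3 fell without DMSO replicate 3 and Sardomozide replicate 2.

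Of 37 tested genes of the ATF4 stress-response list, 8 rose, 1 fell and 28 did not pass, and adjusted over the list alone 12 rose and 2 fell. Camera called the list (adjusted p = 0.00147), with adjusted p = 0.416 with an estimated correlation, and fry gave an adjusted p of 0.0082. Stc2, Ppp1r15a, which encodes a phosphatase subunit that restores translation, and Fgf21, a hormone gene induced by stress, rose with log2 fold changes of 0.92 ± 0.096, 0.61 ± 0.056 and 0.48 ± 0.05. Atf5 fell (−0.33 ± 0.042). Among 26 genes of the endoplasmic reticulum stress list, 2 rose, Atf6 and Herpud1, and 4 fell, with 2 and 6 adjusted over the list alone (camera adjusted p = 0.0687). The falls, Pdia6 and Dnajb11 among them, numbered 0, 1 and 0 without DMSO replicate 1, DMSO replicate 3 and Sardomozide replicate 3. Of 21 heat shock genes 5 rose and 3 fell, and 6 and 3 adjusted over the list alone, with Hspa4 higher and Hspb8 lower (camera adjusted p = 0.774; the mean lay below 0 and the median and test above). Of 31 proteasome genes 1 rose, Psmd8, and 0 fell, as when adjusted over the list alone (camera adjusted p = 0.809; the median lay below 0 and the mean and test above). Psmd8 had an edgeR adjusted p of 0.0761 without DMSO replicate 3. Of the heat shock genes 2 or 3 rose without any library other than Sardomozide replicate 2. Without Sardomozide replicate 2, 2 proteasome genes rose, and without DMSO replicate 1 or Sardomozide replicate 3, 2 ATF4 list genes fell.

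Of 29 p53 target genes, 12 rose, 3 fell and 14 did not pass, and adjusted over the list alone 13 rose and 4 fell. Ccng1, Aen and Eda2r rose with log2 fold changes of 0.53 ± 0.048, 0.49 ± 0.05 and 0.39 ± 0.044, and Phlda3 fell (−0.29 ± 0.047). Camera called the list (adjusted p = 0.0242), with adjusted p = 0.416 with an estimated correlation, and fry gave an adjusted p of 0.0082. The estimated correlation was 0.00037, under the preset 0.01, so a higher correlation does not account for the larger camera p. Without DMSO replicate 2 or Sardomozide replicate 1 the list's camera adjusted p was 0.0679 and 0.0551. Of 45 cell cycle genes, 12 rose, 0 fell and 33 did not pass, and adjusted over the list alone 14 rose. The rises were small, with log2 fold changes of 0.20 ± 0.046 for Rrm1, a subunit gene of ribonucleotide reductase, 0.23 ± 0.057 for the spindle gene Tpx2, 0.22 ± 0.053 for Racgap1 and 0.40 ± 0.1 for Cdca8. Camera called the list (adjusted p = 0.000628), with adjusted p = 0.792 with an estimated correlation of 0.34, and fry gave an adjusted p of 0.189. Of 19 markers of undifferentiated myoblasts and reserve cells, 2 rose, Id2 among them, and 4 fell, Spry1 and Rbl2 among them, with the same counts adjusted over the list alone (camera adjusted p = 0.247). Of 12 replication-dependent histone genes 1 rose, Hist1h2bc (0.45 ± 0.061), and 0 fell, as when adjusted over the list alone (camera adjusted p = 0.239). The count of cell cycle genes that rose was 5, 6 and 6 without DMSO replicate 1, DMSO replicate 3 and Sardomozide replicate 3, and 19 without Sardomozide replicate 1, and 1 fell without DMSO replicate 2 or Sardomozide replicate 2. Of the markers of undifferentiated cells 1 rose without DMSO replicate 1, 2 or 3 or Sardomozide replicate 2, and 2 fell without DMSO replicate 3. Without DMSO replicate 1 or Sardomozide replicate 3, 2 histone genes rose.

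Of 46 nuclear genes of oxidative phosphorylation, 10 rose, 0 fell and 36 did not pass, and adjusted over the list alone 11 rose. Atp5b, Cyc1, Cycs and Uqcrc1 rose with log2 fold changes of 0.27, 0.25, 0.23 and 0.19. Of 19 regulators of mitochondrial biogenesis 4 rose and 0 fell, as when adjusted over the list alone, led by the coactivator gene Ppargc1a (2.72 ± 0.31 to 5.56 ± 0.293 CPM, edgeR adjusted p = 0.000227). Of 25 cholesterol synthesis genes 0 rose, 7 fell and 18 did not pass, and adjusted over the list alone 9 fell. Mvd, Ebp and Nsdhl fell with log2 fold changes of −0.39, −0.34 and −0.26. Camera called these 3 lists (adjusted p = 0.023, 0.0367 and 0.00965), with adjusted p = 0.809, 0.416 and 0.79 with an estimated correlation. The estimated correlations were 0.32, −0.029 and 0.29, where the preset was 0.01. Fry, by direction, did not call the oxidative phosphorylation and cholesterol lists (adjusted p = 0.24 and 0.0947) and gave 0.0154 for the biogenesis list. The oxidative phosphorylation call was lost without DMSO replicate 3 or Sardomozide replicate 2 or 3 (camera adjusted p = 0.165, 0.111 and 0.0559), the biogenesis call without DMSO replicate 1 or 3 or Sardomozide replicate 3 (0.0555, 0.0582 and 0.076), with the stricter filter (0.203) and after GC and length correction (0.0786), and the cholesterol call without DMSO replicate 3 or Sardomozide replicate 3 (0.0879 and 0.0559). The counts of genes were also lower in some fits without a library, which have fewer samples. Of the biogenesis genes only Ppargc1a rose without DMSO replicate 1 or DMSO replicate 2, and 2 rose without Sardomozide replicate 1 or 3. Of the oxidative phosphorylation genes 5, 6 and 6 rose without DMSO replicate 1, DMSO replicate 3 and Sardomozide replicate 2.

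Among other metabolic lists, camera called none. Of 14 fatty acid synthesis genes 1 rose and 4 fell, with Fads2 and Acly lower (log2 fold changes −0.39 and −0.24; camera adjusted p = 0.436), and the same counts were found adjusted over the list alone. Of 38 genes of the citric acid cycle and fatty acid oxidation 5 rose and 6 fell, and 8 and 9 adjusted over the list alone, with Cd36, Hadh and Ucp2 lower and Dlst higher (camera adjusted p = 0.774). Of 27 glycolysis genes 1 rose and 4 fell, and 2 and 4 adjusted over the list alone, with Pfkm, the muscle phosphofructokinase gene, and Pdk4 lower (−0.35 ± 0.043 and −0.63 ± 0.081; camera adjusted p = 0.103). Without Sardomozide replicate 1 the glycolysis list had a camera adjusted p of 0.0102. Of 29 mitochondrial ribosome genes 1 rose, Mrps7, and 0 fell, and adjusted over the list alone 0 rose and 0 fell (camera adjusted p = 0.104). Mrps7 lost its call when any of the libraries other than DMSO replicate 2 was left out (edgeR adjusted p = 0.073 to 0.194), and with DESeq2 and limma-voom (0.0608 and 0.0538). Of the citric acid cycle and fatty acid oxidation genes 2 or 3 rose, and of the fatty acid synthesis genes 0, without any library other than Sardomozide replicate 2 for the former and Sardomozide replicate 1 for the latter. Of the glycolysis genes 0 rose and 2 fell without DMSO replicate 2 or 3, 2 rose and 8 fell without Sardomozide replicate 1, and 2 rose without Sardomozide replicate 3. Mitochondrially encoded genes are not analysed here.

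Of 44 extracellular matrix genes, 2 rose, 11 fell and 31 did not pass, as when adjusted over the list alone. Timp1, the crosslinking enzyme gene Lox and Thbs1 fell with log2 fold changes of −0.37 ± 0.05, −0.31 ± 0.052 and −0.35 ± 0.064, and Timp2 rose (0.23 ± 0.043). Of 33 NRF2 and antioxidant genes, 2 rose, 10 fell and 21 did not pass, and adjusted over the list alone 2 rose and 12 fell. Fth1, which encodes ferritin heavy chain, fell from 1452 ± 43.9 to 1130 ± 13.1 CPM, and Cat, the catalase gene, fell by 13.4%, whereas Sod2 and Osgin1 rose (0.23 ± 0.048 and 0.32 ± 0.069). Camera called both lists (adjusted p = 0.0367 and 0.0499), with adjusted p = 0.809 and 0.416 with an estimated correlation. The estimated correlations were 0.28 and −0.0094, where the preset was 0.01. Fry gave adjusted p = 0.328 and 0.0131. The matrix call was lost without DMSO replicate 1 or 3 or Sardomozide replicate 1 or 3 (camera adjusted p = 0.15, 0.128, 0.099 and 0.163), and the antioxidant call without DMSO replicate 1, 2 or 3 or Sardomozide replicate 1 or 3 (0.0597, 0.0796, 0.0582, 0.099 and 0.0709), with the stricter filter (0.055), after thinning (0.0609) and after GC and length correction (0.0786). Of 26 TGFβ and BMP target genes 3 rose and 8 fell, as when adjusted over the list alone, with Ctgf falling from 398 ± 36.8 to 252 ± 5.41 CPM (camera adjusted p = 0.104, and 0.0443 with the stricter filter). Of the matrix genes 6 and 7 fell without DMSO replicate 1 and DMSO replicate 3, and 1 rose without any library other than Sardomozide replicate 3. Of the antioxidant genes 5 fell without DMSO replicate 1, DMSO replicate 2 or Sardomozide replicate 3. Of the TGFβ and BMP target genes 1 rose without DMSO replicate 1 or 2, and 5 fell without DMSO replicate 3 or Sardomozide replicate 1.

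The remaining lists were not called by camera. Of 27 insulin and mTOR signalling genes 4 rose and 4 fell, and 5 and 4 adjusted over the list alone, with Akt2 higher (log2 fold change 0.47 ± 0.042) and Igfbp4 lower (−0.57 ± 0.05; camera adjusted p = 0.809, with a median and test above 0 and a mean below). Of 25 atrophy and ubiquitin genes 4 rose and 4 fell, as adjusted over the list alone, with Fbxo32, a ubiquitin ligase gene induced in wasting muscle, lower (−0.27 ± 0.046) and Gadd45a higher (0.24 ± 0.045; camera adjusted p = 0.774, with a median and test above 0 and a mean below). Of 41 autophagy and lysosome genes 3 rose and 6 fell, as adjusted over the list alone, with Wipi1 and Ulk2 lower and Hexa higher (camera adjusted p = 0.952, with a median and test above 0 and a mean below). Of 23 myokine genes 3 rose, Fndc5 among them, and 2 fell, Dcn among them, and 4 and 4 adjusted over the list alone (camera adjusted p = 0.848, with a median below 0 and a mean and test above). Of 25 immediate early genes 4 rose, Dusp4 among them, and 6 fell, Dusp6 and Egr2 among them, as adjusted over the list alone (camera adjusted p = 0.793). Of 21 hypoxia genes 4 rose, Egln3 among them, and 1 fell, as adjusted over the list alone (camera adjusted p = 0.247, and 0.0107 without Sardomozide replicate 3). Of 30 interferon response genes 0 rose and 1 fell, Ifi27, and of 20 inflammation genes 0 rose and 2 fell, Csf1 and Cx3cl1, with the same counts adjusted over the list alone (camera adjusted p = 0.123 and 0.247). Without Sardomozide replicate 3 the interferon list had a camera adjusted p of 0.017, and Ifi27 had an edgeR adjusted p of 0.0663 without DMSO replicate 1. Counts in other lists of this paragraph moved as well. Of the atrophy genes 1, 2, 2 and 2 rose without DMSO replicate 1, 2 and 3 and Sardomozide replicate 1, and 2 fell without DMSO replicate 1 or 3 or Sardomozide replicate 3. Of the autophagy genes 2 and 3 fell without DMSO replicate 1 and Sardomozide replicate 3, and of the immediate early genes 3 fell without Sardomozide replicate 3. Without DMSO replicate 3, 2 insulin and mTOR genes rose and 1 myokine gene fell. Of the hypoxia genes 2 rose without DMSO replicate 1 or 3, and 2 and 0 fell without Sardomozide replicate 1 and 3. Of the interferon genes 0 and 3 fell without DMSO replicate 1 and Sardomozide replicate 3.

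Markers of other cell types were few. Of 7 osteoblast and chondrocyte markers 1 rose, Bglap, with 1, 4 and 1 counts with DMSO and 12, 14 and 14 with Sardomozide, and 1 fell, Spp1 (809 ± 92 to 532 ± 50.6 CPM), as adjusted over the list alone (camera adjusted p = 0.827, with a mean above 0 and a median and test below). Bglap shares sequence with Bglap2, another osteocalcin gene that rose, so its counts are uncertain. The call of Spp1 was lost without Sardomozide replicate 1 (edgeR adjusted p = 0.0686). That of Bglap was lost without DMSO replicate 1 or 3 (edgeR adjusted p = 0.0928 and 0.102). It was also lost without Sardomozide replicate 2 or 3 (0.0596 and 0.0759) and with no filter (0.051). Of 8 smooth muscle markers 0 rose and 2 fell, Tagln and Smtn, as adjusted over the list alone (camera adjusted p = 0.391), and Smtn lost its call without DMSO replicate 1 or 3 or Sardomozide replicate 2 or 3 (edgeR adjusted p = 0.115, 0.13, 0.131 and 0.0769) and after GC and length correction (0.0582). The lists of endothelial, macrophage, adipocyte and epithelial markers had 4, 3, 4 and 2 tested members, too few for the list test. Egfl7 rose among the endothelial markers and Itgam, with 11, 8 and 18 counts with DMSO and 55, 33 and 28 with Sardomozide, among the macrophage markers, and these were the only calls in the 4 lists, also adjusted over each list alone. The endothelial median lay below 0 and its mean above. Egfl7 lost its call in 5 of the 6 fits that left out a library (edgeR adjusted p = 0.068 to 0.191), with limma-voom (0.0737) and after thinning (0.0631), and Itgam without DMSO replicate 1 or 2 or Sardomozide replicate 1 (0.081, 0.135 and 0.132). Without Sardomozide replicate 1, 3 smooth muscle markers fell and 1 adipocyte marker rose.

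**Figure D4:**
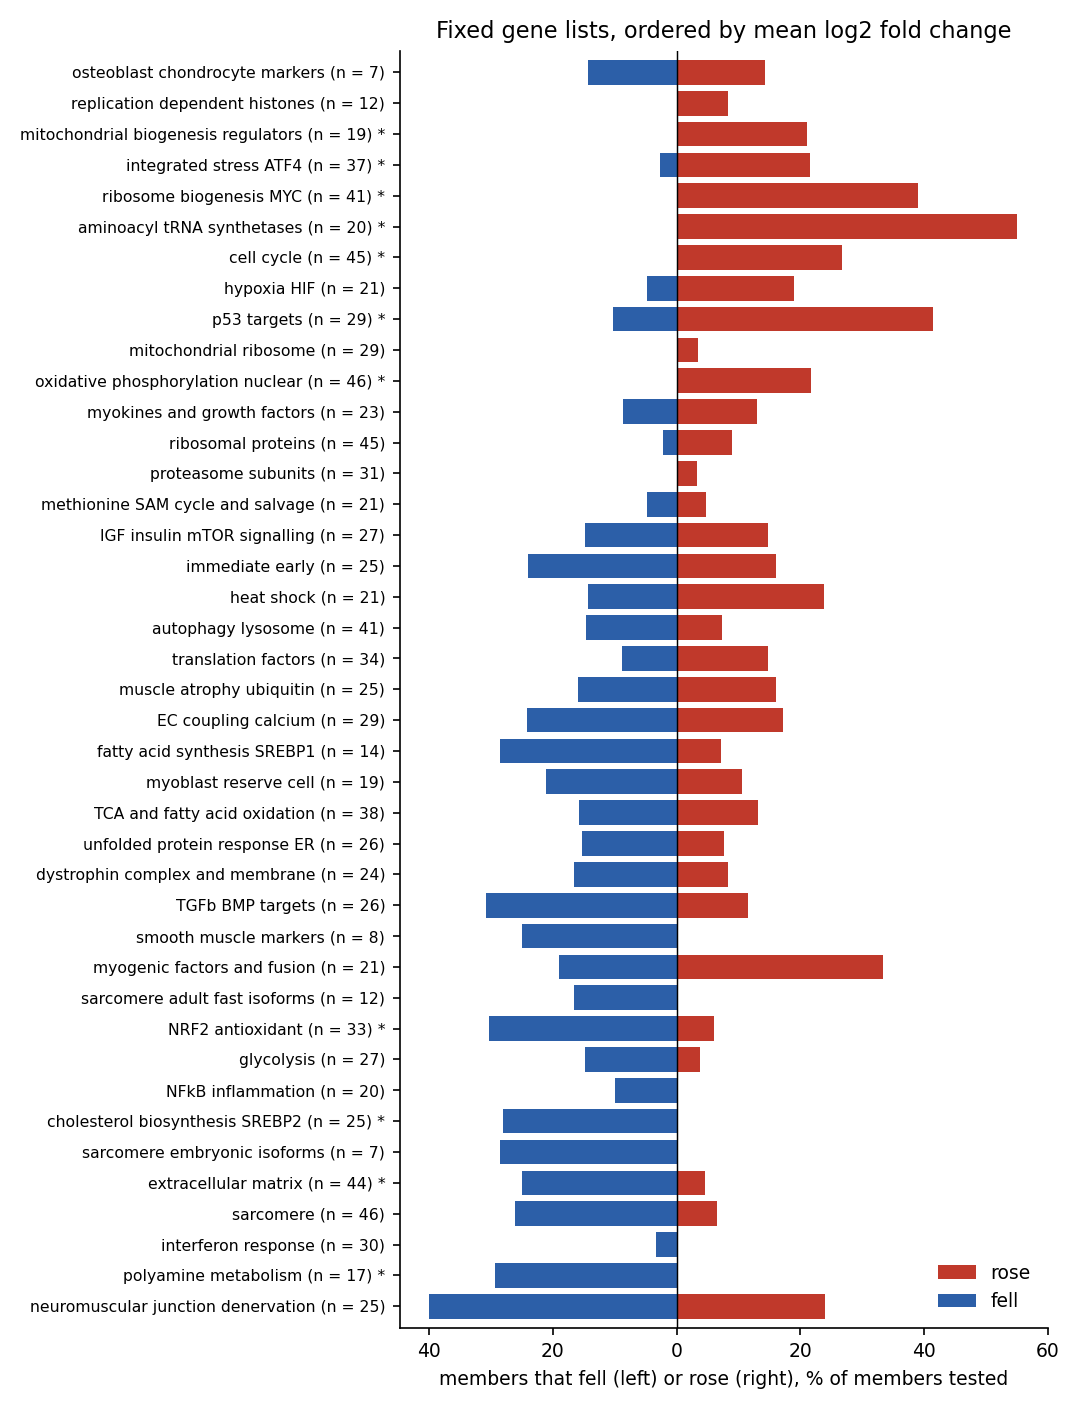
For each of the 41 tested lists, the percent of tested members that fell (blue, left) or rose (red, right) in edgeR's test, with the number of members tested in brackets and lists ordered by mean log2 fold change. Stars mark the 11 lists that camera called at an adjusted p under 0.05 with the preset correlation, 7 up and 4 down, and with an estimated correlation 0 lists were called.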

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

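Thinning, the GC and length correction and the fit without Rn45s were chosen after the data were seen, and the other settings were planned. The count of 2135 genes stayed within 1.5 times under other scaling factors, DESeq2 (2050), limma-voom (2029), no filter (2389), a stricter filter (2026), estimation without robustness (2063), thinning (2067), the correction (2206, with 1224 higher and 982 lower, where the count of 2135 had 1030 and 1105) and without Rn45s (2138), and no call shared with any of these fits had the opposite direction. A test against a 1.2-fold change left 203 genes (82 higher, 121 lower, 149 of them at least 1.5-fold), and an adjusted p under 0.01 left 1079 (501 higher, 578 lower, 193 at least 1.5-fold), both by construction. The stricter filter left 139 genes of at least 1.5-fold instead of 295, among the 10603 genes it tested. Leaving out 1 library, which also leaves fewer samples, gave 1326 to 1952 genes (620 to 927 higher, 706 to 1025 lower, 220 to 287 at least 1.5-fold) and 5 to 11 called lists. The lowest count of genes came without DMSO replicate 1 (1326), and the lowest count of lists without DMSO replicate 3 (5, with 672 genes higher). The replicate numbers did not pair the libraries: deviations of same-numbered libraries from their group means correlated at 0.022, −0.023 and −0.018 across genes, and not every library correlated best with its own number. With the replicate number as a block, edgeR gave 1820 genes and DESeq2 1071 (467 higher, 604 lower), and camera called 7 lists; the cause was not tested. Camera gave adjusted p = 0.0515 for the polyamine list, 0.0575 for mitochondrial biogenesis, 0.0632 for the matrix and 0.0535 for the antioxidant list with that block, and Rn45s had 0.000611 by edgeR and 5.39e-09 by DESeq2. Camera with an estimated correlation called 0 lists, with 4 at an unadjusted p under 0.05. The estimates for the p53, mitochondrial biogenesis and antioxidant lists (0.00037, −0.029 and −0.0094) lay under the preset 0.01. A higher correlation therefore does not account for the larger p of those lists. Fry called 8 lists by direction, 7 of them also called by camera with the preset correlation. Fry's mixed test, which asks another question, called 39. Of 186 genes followed, 165 passed, 26 of these lost their call in at least 1 fit without a library, and 0 reversed. Of the 165, 117 did not pass the test against a 1.2-fold change, so for them a change above that size was not shown. Depth limits what can be said of genes with few counts, such as Bglap, with 1, 4 and 1 counts in the DMSO libraries.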

Other observations

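The tests of Amd1 counts, of shared Amd1 and Amd2 sequence and of undifferentiated cell markers were chosen after the results they bear on were seen. The ERK, YAP and CREB target lists were also chosen after the first results, with their criteria written before their own values were computed.

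Some genes of growth factor signalling moved beside the groups already described. Spry2 and Etv4, which are induced by ERK signalling, fell with log2 fold changes of −0.35 ± 0.053 and −0.50 ± 0.1, as did Dusp6, Egr2, Spry1 and Etv5. Ccnd1, a cyclin gene of the ERK list that is not in the cell cycle list, fell too (−0.56 ± 0.15, edgeR adjusted p = 0.0455). Dusp4 and Epha4 rose (0.53 ± 0.071 and 0.63 ± 0.096). Among genes described as targets of YAP and TEAD, Ctgf, Nt5e, Asap1, Ccdc80 and Axl fell with log2 fold changes of −0.66, −0.48, −0.33, −0.28 and −0.14. Among genes described as targets of CREB, Nr4a3, Ppargc1a and Sik1 rose (1.58, 1.03 and 0.19) and Pde4d and Pde7b fell (−0.30 and −0.65). Sik1 lost its call without DMSO replicate 1 (edgeR adjusted p = 0.0576).

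Lower expression of ERK targets as a group, lower expression of YAP and TEAD targets as a group, and higher expression of CREB targets as a group were each put as a hypothesis. They were tested on 19, 18 and 19 members whose values had not been printed, although the CREB and ERK lists held Lif, Irs2, Inhba and Bdnf, known from the fixed lists not to have passed. None met the criterion of a fry p, adjusted over the 3 lists, under 0.05 in the stated direction. The ERK list had a median log2 fold change of −0.06 (95% bootstrap interval −0.12 to 0.04, 1 rose and 3 fell, fry adjusted p = 0.0706), and the YAP and TEAD list one of −0.07 (−0.12 to 0.03, 0 rose and 4 fell, fry adjusted p = 0.115). The CREB list pointed down, against its hypothesis, with a median of −0.09 (−0.19 to 0.057, 1 rose and 2 fell, fry adjusted p = 0.0706). The criteria had also taken a p of 0.05 or more, or the opposite direction, as evidence against a hypothesis. By those criteria all 3 lists counted against their hypotheses, the CREB list by its direction as well. After the values were seen, the part on p was judged too strict, since a p that misses the threshold excludes no effect, and the ERK and YAP hypotheses stay open. That reason does not bear on the direction of the CREB list, whose unadjusted fry p was 0.0381 downwards, against 0.0471 for the ERK list. The bootstrap intervals of these lists resampled genes and hold no spread between libraries, so they set no limit on a shift of a list. A small rise of the CREB list, or a rise of some CREB targets, stays open.

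The count of 2135 genes was set against technical explanations. The treated libraries had larger totals on average, and thinning all libraries to the smallest total left 2067 genes, which argues against depth as the whole cause. Removing each library's trend on GC content and length, known for 96.3% of the genes tested, gave 2206 genes, 1959 of them among the 2135. Of the 2206, 1224 were higher and 982 lower, so that the balance changed side from 1030 and 1105, but the size of the count did not fall, which argues against those trends as the whole cause. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2135 genes, 1 of the 10 splits reaching that number, and the highest of the others gave 0. Each of the others mixes treated and control libraries in both groups, so the 0 does not measure what chance alone would give. Whether the treatment or an unrecorded difference in how the cultures of each group were handled may underlie the count was not tested.

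Counts of Amd1 were near 0 in both groups, at most 3 in a DMSO library, so a drug effect on its transcript cannot account for the absence of reads in the treated libraries. A candidate explanation is that reads shared with Amd2 were not counted. Of the 150-base stretches of the Amd1 transcript, 61.9% also occur in Amd2 and 38.1% do not. The latter could have given reads if the gene is transcribed and if they occur nowhere else. Oaz1, with a pseudogene copy, was also near 0, and 64.1% of its 150-base stretches are not in that copy. The rest of the genome was not searched for the stretches of either gene, so their uniqueness is not known. Hnrnpa1, an abundant transcript in most cells, had 56 to 145 counts. Because the handling of reads with several matches and the annotation are not given, the explanation cannot be told apart from others.

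The small rise of cell cycle genes (median log2 fold change 0.15, 95% bootstrap interval 0.083 to 0.19) held its camera call after GC and length correction (adjusted p = 0.000655, with 3.37e-07 to 0.792 over all settings), which argues against those trends as the whole cause. The upper end of that range is camera with an estimated correlation. The bootstrap intervals of this paragraph resampled genes, so they hold no spread between libraries. Fry gave the cell cycle list an adjusted p of 0.189. A larger share of undifferentiated cells in the treated cultures could also raise these genes. The criterion written against this, that the interval of markers of such cells lies below that of the cell cycle genes, was met: the markers had a median of −0.0376 (−0.15 to −0.0015). Pax7, a narrower marker, was added to the reading only after these values were seen. It was at 0.09 ± 0.052, which does not lie below the cell cycle interval by more than its spread, and Myf5 was at −0.15 ± 0.1. Whether myotubes make the other markers too was not measured. The explanation is left open on these grounds, and because the intervals hold no spread between libraries. By the written criterion alone the list as a whole counted against it.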
